A study of Mus musculus with 5 samples.

How the data were processed

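RNA from thoracic aorta of male C57BL/6 mice was measured on 5 Affymetrix Mouse Genome 430 2.0 arrays, which read each transcript with sets of short 3′ probes called probe sets. Each array held RNA pooled from 6 to 8 aortas, and the labels describe the pools as independent. The groups, taken from the genotype label, were 2 arrays of non-transgenic littermates and 3 arrays of mice that carry P467L, a dominant negative form of human PPARγ, under the smooth muscle myosin heavy chain promoter.

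The deposited values were on the log2 scale and were made with RMA in Affymetrix Power Tools, per the submitters' processing notes; their versions were not given in the sources used here. RMA corrects background, forces all arrays to 1 distribution by quantile normalization and summarises the probes of a set, so a shift shared by most transcripts would have been removed. The values carried 2 decimals, and 514 probe sets had no spread left within either group after that rounding. Values ran from 3.03 to 14.99, and the number of arrays limits the precision of every comparison.

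Probe sets were named from the platform's annotation table, with symbols updated through NCBI gene numbers from the GRCm38.p6 gene table, which was used only for names and for which genes neighbour each other. Of 45037 probe sets, 34945 had 1 gene, 932 had several and were not named, and 9160 had none in the table. The 64 Affymetrix control probe sets were left out of all tests. The named probe sets covered 18194 genes. For gene lists, each gene was read from its single-gene probe set with the highest mean over the 5 arrays.

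The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no trend and no covariate), with Benjamini-Hochberg adjustment over all 45037 probe sets and a threshold of 0.05. The estimated prior had 1.23 degrees of freedom, giving 4.23 in total per test. Differences are P467L minus non-transgenic on the log2 scale, with the standard error (SE) of the moderated fit. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 35 lists with at least 5 measured genes, and again with an estimated correlation and with fry. The result of 1 uncalled list is not reported here. Of 1128 list entries, 1127 were matched to a gene number. The members of each list were also adjusted over that list alone. Lists share genes and no correction was made across the 35 lists, so the error rate over all these separate adjustments is not controlled. A further list of Y-linked genes and Xist was used only to check the labels: in 5 of 5 arrays a Y-linked gene exceeded Xist. Levels of different probe sets are not directly comparable, so the check is a rough one.

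The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. That rule took every Pparg probe set. It took per direction the 10 genes with the largest difference among probe sets past the threshold, in which the brighter group lay at or above the median level and the ranges of the groups did not overlap, filled up to 10 by smallest p where fewer passed. It also took every gene of a list drawn from the literature on this transgene, and of each list the members past the threshold, or the 2 with the smallest p where none passed. Genes that passed only when adjusted over the list alone, the transcripts in which single arrays stood apart, and Acta2, Myh11, Tagln, Acta1, Mb, Myl2, Cyp26b1, Unc13c and the neighbours of Tnnc1 singled out were named after their values were seen.

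The pipeline was tested on simulated data for this comparison, with the observed residual SDs. In it 200 of 45037 probe sets, drawn from those above the median level, were changed at once. It called 50.5% of probe sets changed by 1 log2 unit, 87% of those changed by 2 and 97% of those changed by 4. With the median residual SD for all probe sets it called 100% at each size. The rates depend on these settings and are not the power of the real comparison. In a second test a list of genes among 18194 was shifted by 0.5 in either direction, and its direction was recovered each time. This test checks the sign only. Its genes were drawn independently, unlike real lists, whose correlation was estimated at 0.723 for oxidative phosphorylation and 0.307 for lymphocyte markers. The shift was also larger than the median difference of any real list.

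The alternatives were the replicate number as a block, median centring, a second quantile normalization, 2 filters on dim probe sets, a variance trend with robust estimation, array weights, leaving out each array in turn, other thresholds, 1 probe set per gene, and other list tests. A fit of 3 arrays without the 2 that stood apart, the level of Malat1 as a covariate, and a gene-by-gene estimate of array weights were added after the data were seen. No scan date or batch was given in the sources used here, and none was modelled.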

Results

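Thoracic aortas of mice with dominant negative PPARγ in smooth muscle were compared with those of non-transgenic littermates, to find which transcripts differ when this nuclear receptor, a regulator of lipid metabolism that is also active in the vessel wall, is interfered with in the smooth muscle layer. There were 2 non-transgenic and 3 P467L arrays, each a pool of 6 to 8 aortas. Median log2 values were 6.25 in both non-transgenic arrays and 6.17, 6.23 and 6.23 in P467L replicates 1 to 3. Acta2, a marker of contractile smooth muscle, had a mean of 14.8 in both groups, near the highest value of all arrays, 14.99.

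Single arrays stood apart in certain transcripts. P467L replicate 1 correlated with the other arrays at 0.985 to 0.991, while the remaining arrays reached 0.997 among themselves, and the first principal component, with 62.7% of the variance, set it against the others. In that array 842 probe sets lay at least 1 log2 unit below all others and 0 lay as far above. Malat1, a nuclear noncoding RNA, measured 8.03 there against 9.45 to 9.87 elsewhere, and Neat1 measured 10.6 against 11.75 or more. Stomach transcripts were highest in non-transgenic replicate 2: Gkn2, a gastric secreted protein, measured 13.3 against 8.79 to 10.2 in the other arrays, and Chia1, a gastric chitinase, 11.5 against 5.50 to 7.70. In that array 56 probe sets lay at least 1 log2 unit above all others.

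**Figure D1:**
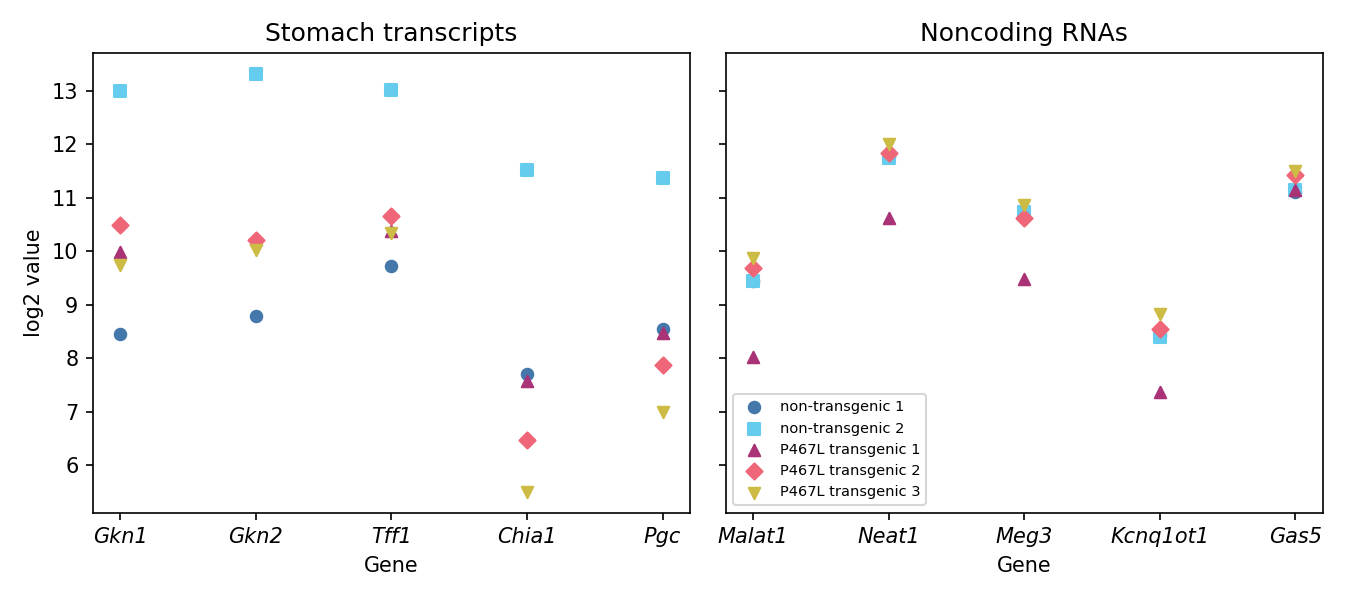
Log2 values of 5 stomach transcripts (left) and 5 noncoding RNAs (right), with genes on the horizontal axis and 1 point per array. Non-transgenic replicate 2 lies above the other arrays in each stomach transcript (Gkn2 13.3), and P467L replicate 1 lies below them for Malat1 (8.03), Neat1, Meg3 and Kcnq1ot1 but not for Gas5.

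P467L aortas had higher levels of Tnnc1, the troponin C of cardiac and slow skeletal muscle, at 10.9 ± 0.20 (SD, n = 3) against 6.08 ± 0.46 (SD, n = 2), a 27.6-fold difference as measured; the non-transgenic mean lies below the array medians and was not tested against background, so the fold could be larger. Sbspon, a secreted protein with somatomedin B and thrombospondin domains, was higher by 3.13 log2 units (SE 0.17), or 8.78-fold, and Acan, the core protein of the cartilage proteoglycan aggrecan, by 1.79 (SE 0.07). Lower levels were measured for P2rx1, an ATP-gated cation channel of smooth muscle, at -1.57 (SE 0.07), for Fam81a at -1.29 (SE 0.05), and for Myoz2, a Z-disc protein of striated muscle, at -1.18 (SE 0.08). None of these passed the test: limma called 0 of 45037 probe sets at an adjusted p of 0.05. The smallest adjusted p was 0.0953.

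Among genes higher in P467L aortas, the naming rule also took the anion exchanger Slc26a3 at 1.32 (SE 0.07). It took the focal adhesion protein Tes at 1.16 (SE 0.05) and Eps8l2 at 0.94 (SE 0.04). Crispld1 was higher by 0.91 (SE 0.04), the retinoic acid receptor Rarb by 0.83 (SE 0.04), the replication licensing factor Mcm6 by 0.70 (SE 0.03) and the transcription factor Ets2 by 0.62 (SE 0.03). These and Tnnc1, Sbspon and Acan had adjusted p of 0.0953 or 0.0954. Among the lower genes, the mean difference was -0.79 for Pkp4, an armadillo protein of cell junctions, -0.60 for Rarres2, which encodes the adipokine chemerin, -0.47 for Tmcc3 and -0.50 for Cxxc4. Rhobtb1, whose protein binds cullin-3, measured -0.85 (SE 0.07), the microfibril protein Mfap5 -0.95 (SE 0.08) and the noncoding Hoxb5os -0.58 (SE 0.05), with adjusted p of 0.193 for each. Adjusted p was 0.0953 for Fam81a, P2rx1 and Pkp4, 0.126 for Rarres2 and Myoz2, 0.132 for Tmcc3 and 0.133 for Cxxc4. In each of these 20 genes all 3 P467L arrays lay on the same side of both non-transgenic arrays, as the naming rule required. All 20 were taken by smallest p, which favours probe sets whose spread is small, in part by chance, so their SEs may be too small. The median SE over all probe sets was 0.0793, and of the 20 only Tnnc1, Sbspon and Mfap5 lay above it. Other probe sets of Tes, Sbspon, Crispld1, P2rx1, Pkp4, Rhobtb1, Mfap5 and Tmcc3 differed in the same direction. Dim probe sets of Ets2 and Slc26a3 gave -0.03 and -0.06, and a dim one of Cxxc4 gave 0.04.

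**Figure D2:**
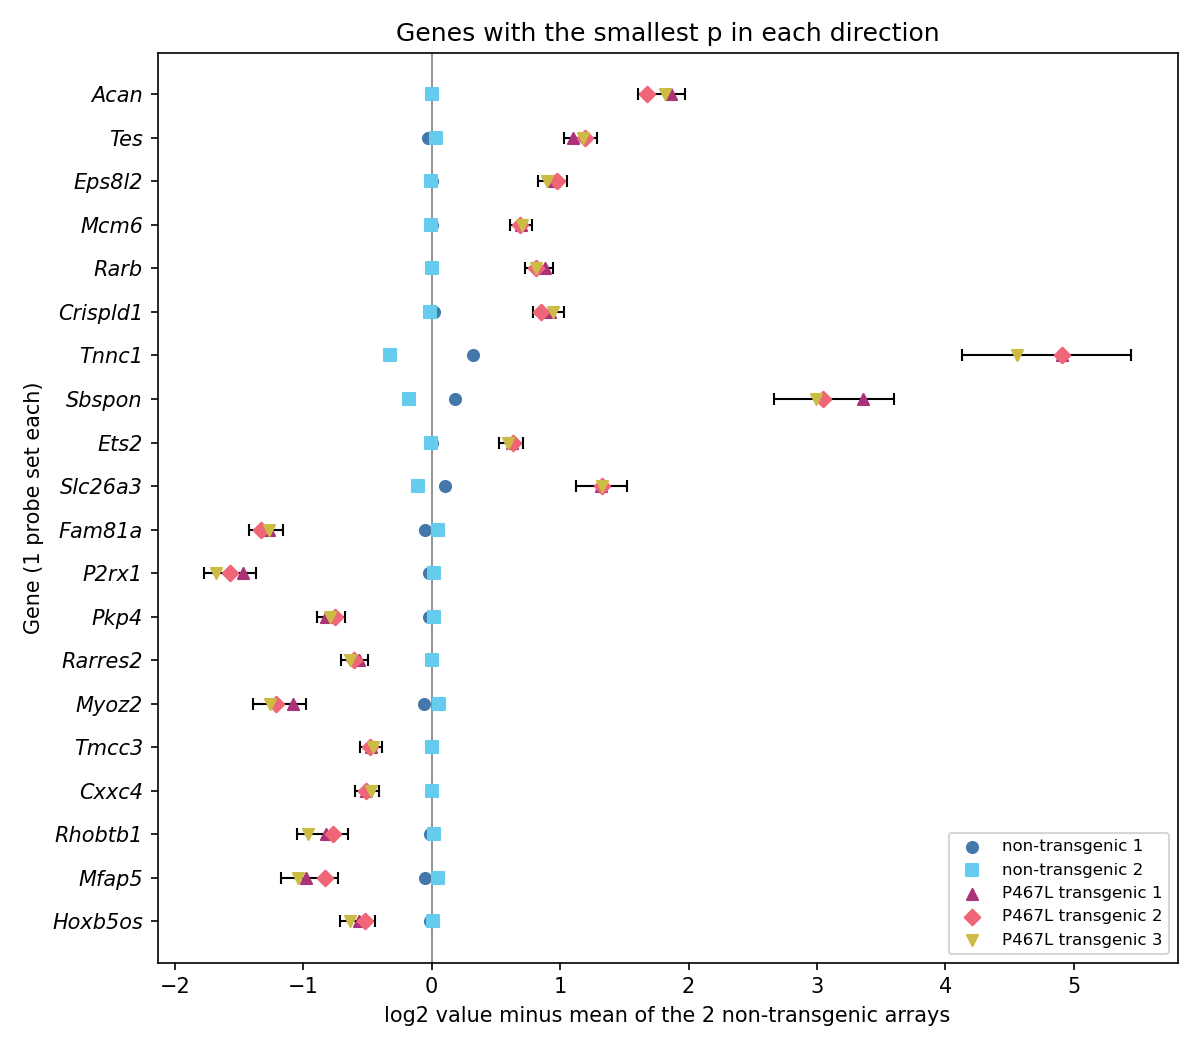
Log2 value of each array minus the mean of the 2 non-transgenic arrays (horizontal axis), for 10 genes per direction (vertical axis). They have the smallest p among single-gene probe sets whose brighter group is at or above the median level and whose ranges do not overlap. Unc13c and Sema3e, with smaller p than some genes shown, were too dim for this rule. Points are arrays and black bars the 95% confidence interval of the group difference. In each gene the 3 P467L arrays lie apart from both non-transgenic arrays because the choice of genes required it. Differences run from 4.79 log2 units for Tnnc1 to -1.57 for P2rx1, and none passed the adjusted threshold.

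At an unadjusted p of 0.05, 3353 probe sets lay past the threshold where 2252 would with no effect, while the split of P467L replicates 1 and 2 against the rest gave 3610. Of the 3353, 2119 were higher and 1234 lower in P467L aortas, which is 63.2% higher, and with each array centred on its median the share was 77.1%. At an adjusted p of 0.10, 17 probe sets were called, 12 higher and 5 lower, with 15 named genes. With 1 probe set per gene 10 genes passed 0.05: Acan, Tes, Eps8l2, Tnnc1, Crispld1, Rarb, Unc13c and Slc26a3 higher, Fam81a and Pkp4 lower. With each array centred on its median 15 probe sets passed, Tnnc1, Acan and Sbspon among them. In 8492 probe sets, or 18.9%, the ranges of the groups did not overlap, where chance gives 20%; 109 of them differed by at least 1 log2 unit, 58 higher and 51 lower.

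Pparg itself, read by 1 probe set, measured 7.29 ± 0.03 (SD, n = 3) in P467L and 7.12 ± 0.29 (SD, n = 2) in non-transgenic aortas, a difference of 0.17 with a 95% interval from -0.19 to 0.53 and an adjusted p of 0.791. Without non-transgenic replicate 2 it was -0.03. Whether this mouse probe set detects the human transgene is not known, so it does not check the labels. Of 18 genes named in advance from the literature on this transgene, 0 passed over all probe sets and 4 passed when adjusted over the list alone: Rhobtb1, Timp4, an inhibitor of matrix metalloproteinases, at -1.14 (SE 0.12), the endothelial nitric oxide synthase Nos3 at 0.47 (SE 0.05) and the extracellular superoxide dismutase Sod3 at 0.39 (SE 0.07). Cul3, which encodes cullin-3, measured -0.11 (SE 0.20) and Rhoa 0.09 (SE 0.04). Rgs5, a pericyte and smooth muscle regulator of G protein signalling, measured -0.31 (SE 0.18) by its brightest probe set and from -0.56 to -0.998 by the other 3; Rgs4 measured 0.33 (SE 0.21). The remaining differences were 0.13 for Kcnmb1, -0.03 for Nos2, 0.03 for Pde5a, 0.00 for Arntl and -0.04 for Cat. The PPARγ targets Fabp4, Cd36 and Retn measured -0.59 (SE 0.32), -0.23 (SE 0.22) and 0.03 (SE 0.23), and the PPAR targets Angptl4 and Pdk4 0.45 (SE 0.25) and 0.02 (SE 0.18). The list as a whole had a camera adjusted p of 0.595.

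PPAR targets of fatty acid oxidation and lipid handling had a median difference of 0.02 over 27 measured genes, 15 higher and 11 lower, with a camera adjusted p of 0.726. Of these, 0 passed over all probe sets and 1 passed when adjusted over the list alone, the fatty acid binding protein Fabp3 at 0.52 (SE 0.07); the triglyceride lipase Pnpla2 measured 0.81 (SE 0.21). The list's median was -0.03 without non-transgenic replicate 2, -0.02 without P467L replicate 1 and 0.09 without non-transgenic replicate 1. PPARγ targets of the white adipocyte had a median of 0.01 over 32 genes and 0 passed either way; Nr1h3, the liver X receptor α, measured 0.55 (SE 0.09), and the camera adjusted p was 0.457. The medians of this list relative to the non-transgenic mean were 0.22 and -0.22 in the non-transgenic arrays and 0.16, -0.08 and -0.09 in P467L replicates 1 to 3. Without non-transgenic replicate 2, the array highest in stomach transcripts, the difference was -0.23. That fit compares the P467L arrays with non-transgenic replicate 1 alone, the higher of the non-transgenic arrays in this list. With all 5 arrays the list had a camera adjusted p of 0.911 with an estimated correlation. The list was drawn from adipocytes while the transgene is under a smooth muscle promoter, so its median does not test PPARγ targets in smooth muscle. The brown adipocyte list had a median of -0.03 over 20 genes with a camera adjusted p of 0.555; Fabp3 was the 1 gene that passed when adjusted over the list alone, and Slc25a20, the carnitine carrier, measured -0.21 (SE 0.10).

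Contractile smooth muscle genes had a median difference of 0.00 over 34 genes (camera adjusted p = 0.506), with 0 past the threshold either way. The brightest probe sets of Acta2, Tagln and Myh11 measured 0.02, 0.02 and -0.03; those of Acta2 and Tagln lie near the top of the scale, where a difference can be hidden, and dimmer ones gave -0.20 and -0.39 for Acta2 and -0.25 for Myh11. In the list, desmin (Des) measured 0.81 (SE 0.13) and the Z-disc protein Ldb3 -0.39 (SE 0.07). The 20 regulators of G protein signalling had a median of -0.04 (camera adjusted p = 0.194), with -0.35 (SE 0.07) for Rgs7, 0.47 (SE 0.11) for Rgs19 and 0 past the threshold. Among 37 ion channel and calcium handling genes, 1 passed when adjusted over the list alone, the T-type calcium channel subunit Cacna1h at 0.61 (SE 0.05); the L-type subunit Cacna1c measured 0.43 (SE 0.07), the list median was 0.06 and the camera adjusted p 0.457.

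Receptors and ligands of vascular tone included 3 lower genes that passed when adjusted over the list alone: P2rx1, whose brightest probe set gave -2.01 (SE 0.30), the natriuretic peptide clearance receptor Npr3 at -1.98 (SE 0.31), and endothelin-1 (Edn1) at -0.85 (SE 0.15). The list's median was 0.01 over 33 genes with a camera adjusted p of 0.194; without P467L replicate 1 the median was -0.06 and the adjusted p 0.0482 at the preset correlation, and with all 5 arrays the list had an adjusted p = 0.911 with an estimated correlation. Of 39 genes of nitric oxide and cyclic nucleotide signalling, 5 passed when adjusted over the list alone: the phosphodiesterase Pde1c at 1.80 (SE 0.13), the cGMP-dependent kinase Prkg2 at 1.24 (SE 0.14), Nos3, the adenylyl cyclase Adcy6 at 0.39 (SE 0.07), and caveolin-1 (Cav1) at -0.26 (SE 0.03). That list had a median of -0.03 and a camera adjusted p of 0.893.

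No matrix gene of these lists passed over all probe sets. Among 42 collagens and elastic fibre genes 10 passed when adjusted over the list alone, 6 higher and 4 lower, with fibronectin (Fn1) at 0.41 (SE 0.04) and the brighter Mfap5 probe set at -0.66 (SE 0.06); the median was 0.01 (camera adjusted p = 0.961). Of 39 matrix proteases and inhibitors 3 passed when adjusted over the list alone, tissue plasminogen activator (Plat) at 1.11 (SE 0.07), Timp3 at 0.24 (SE 0.04) and Timp4; the median was 0.07 (camera adjusted p = 0.288). Of 27 osteogenic and chondrogenic genes Acan passed when adjusted over the list alone, the chondrogenic transcription factor Sox9 measured 0.32 (SE 0.06), and the median was 0.06 (camera adjusted p = 0.728).

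TGF-β and BMP signalling had 5 of 38 genes past the threshold when adjusted over the list alone: Bmp2 at 0.69 (SE 0.10), Id4 at 0.58 (SE 0.05) and Tgfb1 at 0.54 (SE 0.09) were higher, and thrombospondin-1 (Thbs1) at -0.92 (SE 0.12) and Tgfb2 at -0.48 (SE 0.08) were lower. The median was 0.01 (camera adjusted p = 0.777). Of 43 Notch, Wnt and Hedgehog genes 6 passed when adjusted over the list alone, all higher, Dkk3 at 0.66 (SE 0.06) and the Wnt receptor Fzd1 at 0.48 (SE 0.05) with the smallest p; the median was 0.06 (camera adjusted p = 0.307). Immediate early genes had 7 of 30 past the threshold when adjusted over the list alone, 6 higher and 1 lower, with Arc at 1.01 (SE 0.09) and Maff at 0.83 (SE 0.08); the median was 0.11 (camera adjusted p = 0.0822). Proliferation genes had a median of 0.02 over 35 genes (camera adjusted p = 0.828); Mcm6 passed when adjusted over the list alone, by a probe set at 0.60 (SE 0.05), while the spindle protein Nusap1 measured -0.46 (SE 0.18).

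Of the 35 lists 4 were called by camera with the preset correlation, each shifted down relative to other genes. None was called with an estimated correlation or with fry's directional test. Fry's test for change in either direction, which does not compare a list with other genes, passed an adjusted p of 0.05 for 19 of the 35. Heat shock genes fell as a list, with a median of -0.10 over 20 genes and a camera adjusted p of 0.00182 (adjusted p = 0.911 with an estimated correlation). Hspa1b at -0.64 (SE 0.06) and Hspa1a at -0.85 (SE 0.10), near-identical chaperone genes whose probe sets can detect both, passed when adjusted over the list alone. The array medians of this list were -0.20, -0.06 and -0.03 in P467L replicates 1 to 3, and the call was lost without replicate 1. Oxidative phosphorylation genes had a median of -0.04 over 46 genes, 35 lower and 11 higher, with 0 past the threshold. The camera adjusted p was 0.00696, and 0.911 with an estimated correlation of 0.723. The array medians were 0.05 and -0.05 in the non-transgenic arrays and 0.03, -0.04 and -0.12 in P467L replicates 1 to 3. P467L replicates 1 and 2 thus lay within the non-transgenic range. Ndufa10 measured -0.18 (SE 0.06) and Uqcrb -0.09 (SE 0.04). Without non-transgenic replicate 1 the list's median was 0.01. With median centring it was 0.00 and the list stayed called (camera adjusted p = 0.0358), so the call is relative to other genes. The call for this list was lost without non-transgenic replicate 1 and without P467L replicate 3.

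Lymphocyte markers fell as a list, with a median of -0.12 over 28 genes and a camera adjusted p of 0.000424 (adjusted p = 0.911 with an estimated correlation); 23 were lower and 0 passed over the list alone. Thy1, also found on fibroblasts, measured 0.56 (SE 0.16) and the B cell receptor Cd22 -0.28 (SE 0.08). Red cell markers had a median of -0.11 over 14 genes (camera adjusted p = 0.0155, and adjusted p = 0.911 with an estimated correlation) and 0 past the threshold. The mitochondrial iron carrier Slc25a37 measured -0.47 (SE 0.17) and the transferrin receptor Tfrc 0.18 (SE 0.07). The non-transgenic array medians of this list were 0.03 and -0.03. The P467L array medians of the red cell list were -0.02, -0.09 and -0.25, its median ran from -0.41 to -0.05 over the alternatives, and its call was lost without P467L replicate 3 and without non-transgenic replicate 1.

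**Figure D3:**
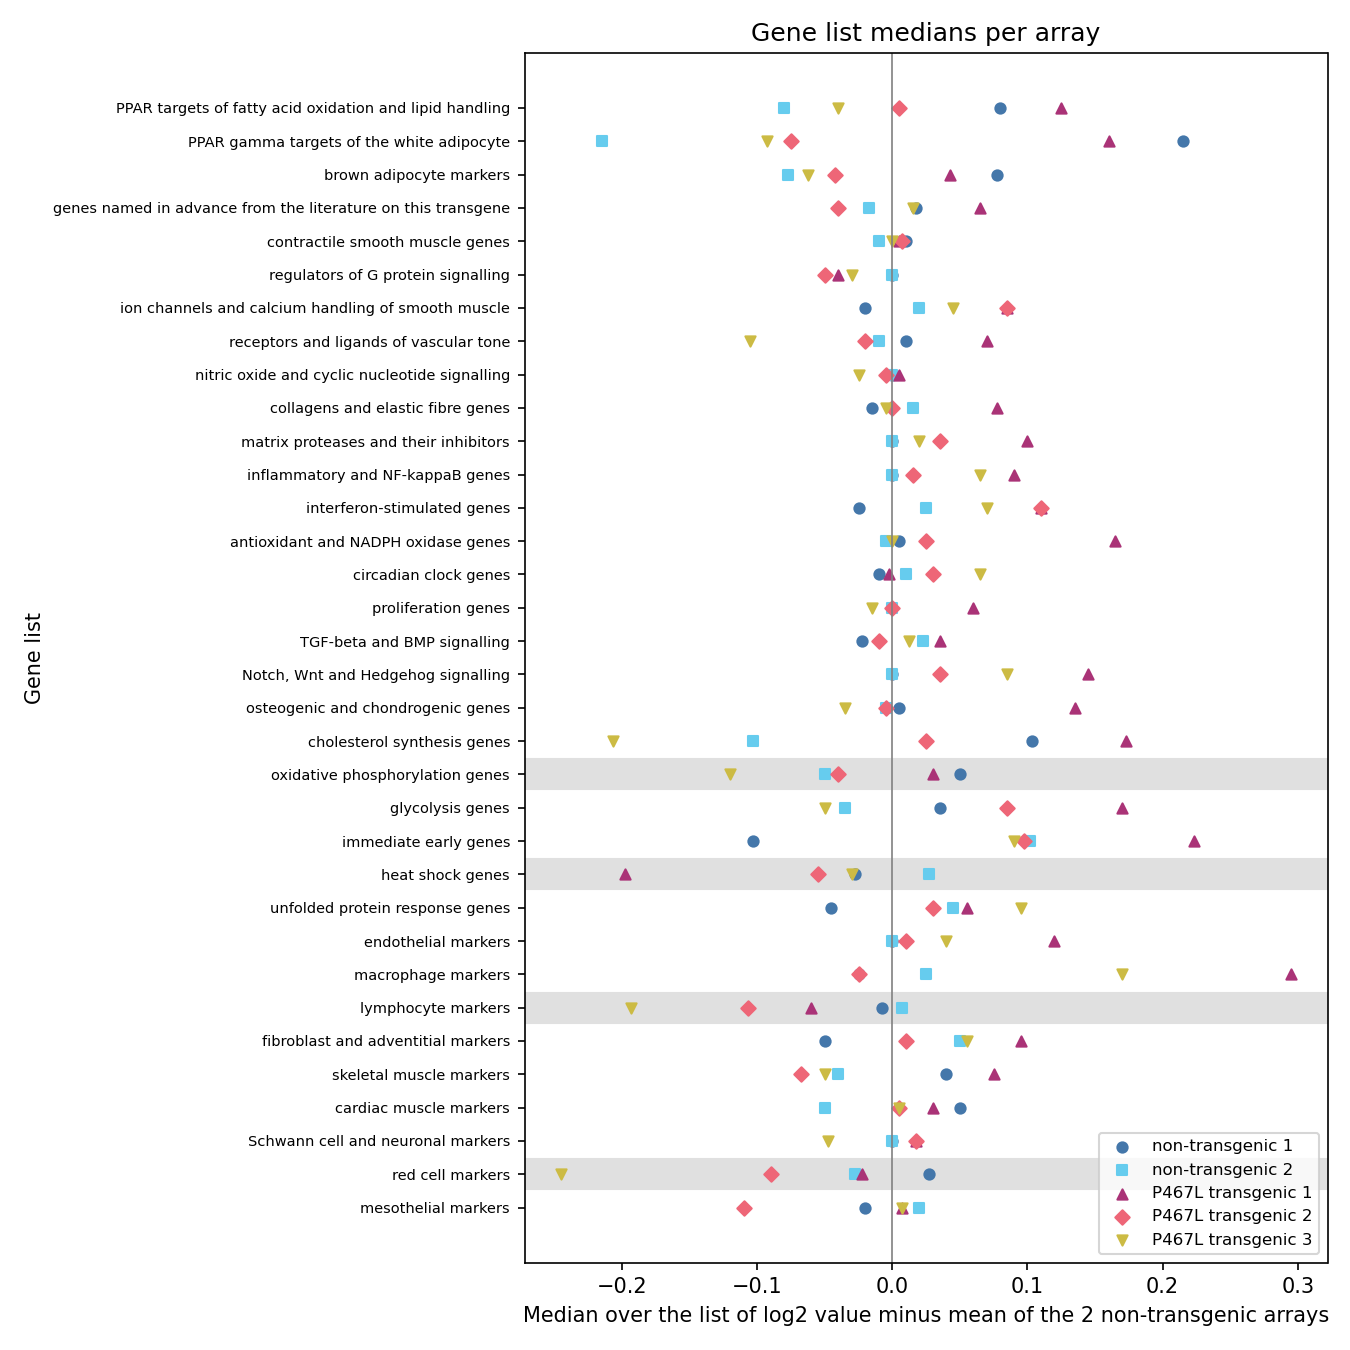
Median over each reported gene list (vertical axis) of the log2 value minus the mean of the 2 non-transgenic arrays (horizontal axis), 1 point per array; grey bands mark the 4 lists called by camera with the preset correlation. The array medians of the lymphocyte list lie below 0 in all 3 P467L arrays, and the white adipocyte list spans 0.22 to -0.22 within the non-transgenic arrays alone.

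With all 5 arrays and 1 probe set per gene, the remaining cell type lists were called neither by camera nor by fry's directional test. Endothelial markers had a median of 0.07 over 29 genes (camera adjusted p = 0.453), and 3 passed when adjusted over the list alone: the endothelial sialomucin Emcn at -1.05 (SE 0.12), the tight junction protein Cldn5 at 0.73 (SE 0.12) and Nos3. Macrophage markers had a median of 0.14 over 30 genes (camera adjusted p = 0.0629), with 0 past the threshold; Laptm5 measured 0.25 (SE 0.08) and C1qb 0.36 (SE 0.12), and the array medians were 0.30, -0.03 and 0.17 in P467L replicates 1 to 3. Of 27 fibroblast and adventitial markers 4 passed when adjusted over the list alone, Cd248 at 0.64 (SE 0.13) and Htra3 at 0.36 (SE 0.05) higher, Tnxb at -0.72 (SE 0.15) and Mfap5 lower; the list's median was 0.06 (camera adjusted p = 0.728). Cardiac muscle markers had a median of 0.00 over 23 genes (camera adjusted p = 0.728), with Tnnt2, cardiac troponin T, at 1.02 (SE 0.10) and Fabp3 past the threshold when adjusted over the list alone. Skeletal muscle markers had a median of -0.03 over 30 genes (camera adjusted p = 0.457); creatine kinase (Ckm) measured 1.33 (SE 0.32) and Pygm 0.42 (SE 0.11). Schwann cell and neuronal markers had a median of -0.01 over 26 genes (camera adjusted p = 0.808), with Uchl1 at 0.53 (SE 0.12) and Cnp at 0.49 (SE 0.12). Mesothelial markers had a median of 0.00 over 20 genes (camera adjusted p = 0.728), with Sulf1 at 0.43 (SE 0.06) past the threshold when adjusted over the list alone and Ezr at -0.23 (SE 0.08).

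Nor were the inflammatory, interferon, antioxidant and unfolded protein lists. Inflammatory and NF-κB genes had a median of 0.08 over 41 genes (camera adjusted p = 0.153), the adhesion molecule Vcam1 at 0.55 (SE 0.09) and the chemokine Cx3cl1 at 0.57 (SE 0.10). Interferon-stimulated genes had a median of 0.11 over 33 genes (camera adjusted p = 0.19), with Parp14 at 0.44 (SE 0.11) and Bst2 at 0.27 (SE 0.08). Antioxidant and NADPH oxidase genes had a median of 0.05 over 36 genes (camera adjusted p = 0.511), with Sod3 and Pgd, at 0.17 (SE 0.04), having the smallest p. Unfolded protein response genes had a median of 0.04 over 27 genes (camera adjusted p = 0.412), with Ddit3 at 0.24 (SE 0.04) and Pdia4 at 0.42 (SE 0.14). In these lists 0 genes passed when adjusted over the list alone.

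Circadian clock, cholesterol synthesis and glycolysis genes likewise had 0 members past the threshold either way. Their medians were 0.01 over 20 genes (camera adjusted p = 0.893), -0.03 over 20 genes (0.457) and 0.07 over 19 genes (0.19). Per1 measured 0.37 (SE 0.12) and Csnk1e 0.21 (SE 0.07), Stard4 -0.37 (SE 0.14) and Tm7sf2 0.15 (SE 0.07), Pfkp -0.33 (SE 0.08) and the glucose transporter Slc2a1 0.33 (SE 0.09). Median, mean and camera direction differed in sign for several lists: camera pointed down while the median was above 0 for the white adipocyte, in-advance, vascular tone, proliferation and TGF-β lists, and down with a mean above 0 for the nitric oxide, skeletal muscle, and Schwann cell lists. Leaving out non-transgenic replicate 2 raised the number of lists called by camera with the preset correlation from 4 to 13, and leaving out non-transgenic replicate 1 lowered it to 2. Without both arrays that stood apart, a fit chosen after the data were seen, it was 10, with 0 probe sets called at an adjusted p of 0.05.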

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

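The tests on stomach and pancreas tissue, nuclear RNA, RNA degradation and striated muscle were chosen only after the patterns had been seen. The test on the neighbours of Tnnc1 was set before its result was seen. For other splits of the arrays, only the count of probe sets apart by at least 1 log2 unit was set beforehand.

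The spike-in controls, which are added in known amount and lie outside the comparison, differed between arrays. Hybridization controls averaged 0.168 log2 units higher in the P467L arrays than in the non-transgenic ones, with all 3 arrays above both. They thus followed the genotype, as did the β-actin difference given below, while that of Gapdh did not. A technical difference of this kind between the groups cannot be told apart from genotype with these arrays. The poly-A controls, added to the RNA before labelling, were 0.437 higher in P467L replicate 1 and 0.0835 higher in P467L replicate 2 than the non-transgenic mean. P467L replicate 3, at 8.209, lay between the non-transgenic arrays at 8.164 and 8.217.

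Stomach transcripts were highest in non-transgenic replicate 2, and several were bright in the other arrays too, with Tff1 at 9.73 to 10.66 there against 13.02. Over 16 measured stomach genes the median excess over the other 4 arrays was 2.33 log2 units, and 9 of the 10 brightest were highest in this array; over the 12 genes whose values had not been seen when the list was written it was 1.88. Pancreatic tissue is argued against, since 15 acinar genes had a median excess of 0.03, although Clps and Pla2g1b had one of 4.42. Stomach tissue or RNA in this pool may therefore be the source of the excess, and Gkn3 and Aqp5, with excesses of 0.00 and 0.02, are exceptions to it. No biological explanation was tested, since the other non-transgenic array lacks the excess.

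P467L replicate 1 held the low probe sets. Degradation read from the 3′ end is argued against, as its 3′ minus 5′ difference for β-actin was 0.53, inside the 0.41 to 0.64 of the other arrays. By genotype, that difference was 0.53, 0.64 and 0.56 in P467L arrays, above the 0.46 and 0.41 of both non-transgenic arrays. For Gapdh the genotypes overlapped, at 0.25, 0.29 and 0.23 against 0.29 and 0.26. Of the 500 probe sets with the largest deficit in P467L replicate 1, 53.2% had no named gene, against 20.3% of all. Malat1, Neat1, Meg3 and Kcnq1ot1 were lower in P467L replicate 1 by 1.19 to 1.58. A smaller recovery of nuclear or unspliced RNA may account for it, but stays open: 7 of 11 listed noncoding RNAs were lowest in this array while their median deficit was 0.145. The 11 include the host genes Gas5, Snhg1 and Snhg11, whose spliced RNA need not be nuclear, so that median is a weak guide. The genotype is shared with P467L replicates 2 and 3, which lack the pattern.

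Tnnc1 and Acan were higher in all 3 P467L arrays. Striated muscle in the pools is argued against: the cardiac list had a median of 0.00167 and the skeletal list -0.0258, and Acta1, Mb and Myl2, abundant in striated muscle, measured -0.28, -0.03 and 0.00, although Tnnt2 and Ckm were higher by 1.02 and 1.33. A change of the whole chromosome region of the size seen for Tnnc1 is argued against too, with a median absolute difference of 0.0833 over the 5 measured genes on each side of Tnnc1, although Sema3g, Nt5dc2, Smim4 and Nisch measured 0.80, 0.42, 0.345 and 0.178; a smaller effect on nearby genes stays open. An effect of the transgene on these genes may remain as a hypothesis, untested beyond these tests.

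The real split of the 5 arrays set 109 probe sets apart by at least 1 log2 unit, and 2 of 10 splits gave as many, the highest other being 181, for P467L replicates 1 and 2 against the rest. With 10 splits the share cannot go below 0.1. At an unadjusted p of 0.05 the real split gave 3353 probe sets and that other split 3610. The real split gave 172 probe sets at an unadjusted p of 0.001, where the highest other split gave 17. It gave 17 at an adjusted p of 0.10, where the highest other split gave 0. These counts by p were not part of the plan. Other splits carry any genotype difference as spread within their groups, so their counts do not show what no effect would give.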

How the results depend on the processing

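The fit of 3 arrays, the Malat1 covariate and the gene-by-gene array weights were chosen only after the data were seen; the other alternatives were fixed beforehand. The count of 0 probe sets at an adjusted p of 0.05 was kept under the replicate block, the second quantile normalization, both filters on dim probe sets, the variance trend, each array left out in turn, the 3 arrays and the Malat1 covariate. It was 15 with each array centred on its median, 10 with 1 probe set per gene, 17 at a threshold of 0.10, 2245 with array weights, whose estimate stopped before convergence at a weight of 34.1 for P467L replicate 2, and 283 with gene-by-gene weights. Fewer tests explain part of the count with 1 probe set per gene; the cause was not tested for the others. The 2 genotypes share replicate numbers 1 and 2, but nothing in the labels ties same-numbered arrays, so they were not treated as pairs. Their deviations from the group means correlated at 0.113 and 0.00814. With 2 non-transgenic arrays, whose deviations mirror each other, these correlations can neither show nor exclude pairing. The replicate block gave 0 probe sets at 0.05, 0 at 0.10 and 3 lists. With 1 array left in a group, its spread is assumed to be that of the other group. Signal over background was not analysed here, and dim probe sets carry the least information.

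The count at an adjusted p of 0.10 was 33 after centring, 29 at or above the median level, 27 at a mean log2 of 6 or more, 29 with the variance trend, 75 with 1 probe set per gene, 7436 with array weights, 1663 with gene-by-gene weights, and 0 under the block, with any array left out, with 3 arrays and with Malat1. At an unadjusted p of 0.05 it was 12940 with array weights, 9153 with gene-by-gene weights, 5157 with 3 arrays, 5857 with Malat1, 1733 with 1 probe set per gene, and 2206 to 4808 with an array left out. The number of called lists was 0 with an estimated correlation, 0 with fry, 7 with the mean of all probe sets, 10 with 3 arrays and 2 to 13 with an array left out. The lymphocyte list was called in every fit except with an estimated correlation and fry; heat shock was lost also without P467L replicate 1, with 3 arrays and with Malat1, and oxidative phosphorylation and red cell markers under the block, without non-transgenic replicate 1 and without P467L replicate 3. Lists not called as reported were called in some fits, all at the preset correlation. Without non-transgenic replicate 2 these were white adipocyte, brown adipocyte, immediate early, inflammatory, interferon, cholesterol, unfolded protein, macrophage and skeletal muscle, and all but inflammatory and macrophage were called with 3 arrays too. Macrophage and inflammatory were called also without P467L replicate 2 and with the mean of all probe sets, and immediate early with that mean and after the second quantile normalization. Glycolysis was called under the block, with array weights and without P467L replicate 3, and vascular tone at a mean of 6 or more, without P467L replicate 1 and with Malat1.

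Differences of the other sign than reported were the following; their cause was not tested. The PPAR target list median was -0.0153 after the second quantile normalization, -0.08 with 3 arrays, -0.0073 with Malat1 and -0.000561 with gene-by-gene weights, and -0.03 to 0.0867 with an array left out. Pparg was -0.05 with 3 arrays and -0.0333 to 0.38 with an array left out. Under the block, the in-advance list was -0.0375, contractile 0.0025, cholesterol 0.09, unfolded protein -0.005, Schwann cell 0.0125, Pde5a -0.085 and Pdk4 -0.095. After centring, brown adipocyte was 0.015, contractile 0.0358, nitric oxide 0.0133, cholesterol 0.0117, oxidative phosphorylation 0.000833, skeletal muscle 0.0142, Schwann cell 0.0333, mesothelial 0.0358 and Nos2 0.01. After the second quantile normalization, white adipocyte was -0.0245, brown adipocyte 0.0121, in-advance -0.00767, TGF-β -0.025, skeletal muscle 0.00767, Schwann cell 0.0183, mesothelial 0.0347, Nos2 0.0157, Pde5a -0.006, Retn -0.00933 and Pdk4 -0.0277. With dim probe sets filtered, mesothelial was 0.0683 under both filters, and G protein regulators 0.005 and vascular tone -0.045 at a mean of 6 or more. With array weights, white adipocyte was -0.0745, in-advance -0.0398, contractile 0.00744, vascular tone -0.0174, collagens -4.69e-05, TGF-β -0.00961, osteogenic -0.00411, cholesterol 0.0239, macrophage -0.0222, Schwann cell 0.0177, Pde5a -0.0875, Retn -0.0297 and Pdk4 -0.30. With 3 arrays, white adipocyte was -0.33, in-advance -0.0375, vascular tone -0.10, antioxidant -0.0125, osteogenic -0.025, glycolysis -0.02, cardiac -0.02, mesothelial 0.0675, Cul3 0.07, Rgs4 -0.015, Retn -0.37 and Pdk4 -0.06. With Malat1, white adipocyte was -0.0838, in-advance -0.0143, vascular tone -0.0548, nitric oxide 0.000448, collagens -0.00514, TGF-β -0.00665, osteogenic -0.0176, Cul3 0.0532, Retn -0.11 and Pdk4 -0.0073. With gene-by-gene weights, white adipocyte was -0.0697, in-advance -0.0372, contractile 0.00671, vascular tone -0.00824, collagens -0.000959, TGF-β -0.00592, cholesterol 0.0103, Schwann cell 0.0162, Pde5a -0.0606, Retn -0.028 and Pdk4 -0.24. With the mean of all probe sets, white adipocyte was -0.0154, in-advance -0.00208, nitric oxide 0.015, circadian -0.0179, TGF-β -0.0104, cholesterol 0.00889 and Schwann cell 0.00875. With an array left out, the ranges were -0.23 to 0.16 for white adipocyte, -0.0917 to 0.12 for brown adipocyte, -0.05 to 0.045 for in-advance, -0.00833 to 0.0125 for contractile, -0.06 to 0.0233 for vascular tone, -0.005 to 0.00667 for nitric oxide, -0.01 to 0.035 for collagens, -0.0025 to 0.0925 for antioxidant, -0.005 to 0.03 for proliferation and -0.0075 to 0.00667 for TGF-β. They were -0.13 to 0.12 for cholesterol, -0.0883 to 0.00667 for oxidative phosphorylation, -0.005 to 0.0733 for unfolded protein, -0.0675 to 0.03 for skeletal muscle, -0.0133 to 0.02 for cardiac, -0.0125 to 0.0125 for Schwann cell and -0.08 to 0.0667 for mesothelial. For genes they were -0.24 to 0.07 for Cul3, -0.09 to 0.03 for Nos2, -0.085 to 0.09 for Pde5a, -0.23 to 0.29 for Retn, -0.095 to 0.17 for Pdk4, -0.53 to 0.07 for Cd36 and -0.13 to 0.05 for Cat. Genes that kept their sign with each array left out but changed in size over 1.5 times were Fabp4 (-0.96 to -0.22), Angptl4 (0.07 to 0.82), Rgs4 (0.07 to 0.59), Rgs5 (-0.405 to -0.16), Kcnmb1 (0.07 to 0.17), Slc25a20 (-0.28 to -0.13) and Nusap1 (-0.73 to -0.19). Over all alternatives, 26 of 97 named genes and 35 of 35 list medians changed in size over 1.5 times in at least 1 fit that kept their sign, so the size of a list median depends on the processing. The medians of the called lists ran from -0.4075 to -0.0525 for red cell, with the largest among probe sets at or above the median level, -0.15 to -0.0075 for heat shock, -0.20 to -0.08417 for lymphocyte and -0.1275 to 0.006667 for oxidative phosphorylation. Of the remaining values, 1286 of named genes and 481 of lists kept their direction and side of the threshold, 117 and 23 passed it newly, and 0 and 16 no longer passed it. Among the fits counted here, named genes could pass newly only after centring (15 probe sets called) and with the array weights (2245) and gene-by-gene weights (283). The fit with 1 probe set per gene, in which 10 genes passed, most of them named genes, is not in these counts. The array weights stopped before convergence, so these new passes are no sign of robustness.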

Other observations

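The test of retinoic acid genes was set before its result was seen; the genes listed by their adjusted p in the first paragraph were chosen after their values were seen.

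Beyond the genes described, Unc13c, a regulator of synaptic vesicle priming, was higher in P467L aortas by 1.37 log2 units (SE 0.07) and Sema3e, a guidance ligand for plexin D1, measured -1.32 (SE 0.07), each with an adjusted p of 0.0953. After median centring, Sphkap, the aminopeptidase Enpep, Cttnbp2 and the Ras-like GTPase Diras2 also passed the threshold of 0.05, higher by 1.82, 1.41, 1.13 and 1.89, with adjusted p from 0.0437 to 0.0488. Their adjusted p as reported for all probe sets ranged from 0.126 to 0.133. Of the 15 probe sets called after centring 10 were among the 17 at an adjusted p of 0.10 without it, and 6 genes were called both after centring and with 1 probe set per gene.

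Higher Rarb beside lower Rarres2 raised the hypothesis that retinoic acid target genes are higher as a group in P467L aortas. Over 22 measured genes of a list that leaves out Rarb, Rarres1 and Rarres2, the median difference was 0.0525. At an unadjusted p of 0.05, 1 gene was higher and 1 lower. These values argue against a shared rise of the listed genes. The list also holds enzymes of retinoic acid synthesis (Aldh1a1, Aldh1a2, Aldh1a3, Rdh10) and receptors (Rara, Rarg, Rxra, Rxrg), and some members are dim. It therefore does not settle whether target genes alone are higher. Cyp26b1, which degrades retinoic acid, measured -0.68.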
